A study of Mus musculus with 21 samples.

How the data were processed

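Gene expression of mouse cells was measured on 21 Affymetrix whole-genome expression arrays, 3 for each of 7 groups. The groups were the androgenetic haploid embryonic stem (ahES) cell lines AH129-5, AH129-N1 and AH129-NC1, the diploid embryonic stem (ES) cell lines CS1-1 and R1, mouse embryonic fibroblasts (MEF) and round sperm. Per the labels, ahES cells and round sperm had been sorted as haploid cells in G0/G1, while no sort was stated for diploid ES cells or MEF. ES cells were grown in N2B27 with 2i and LIF, MEF in DMEM with serum, and round sperm came fresh from testis. The 3 arrays of a group were labelled as biological replicates. No day, batch or pairing of replicate numbers was given by the labels, and arrays sharing a replicate number did not resemble each other beyond their groups, so replicate numbers were not used as pairs.

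The deposited values were log2 MAS5 signals for 45101 probe sets, one value per probe set and array. MAS5 was named in the submitters' processing notes without a version. The base of the logarithm was not given by the labels and was taken from the values: the 2% trimmed mean of the values raised from base 2 was 500 on each of the 21 arrays, the usual MAS5 scaling target. Values ran from 0 to 15.7, with 0 as a floor. No detection calls were used, and the precision of each value is limited by the number of arrays, 3 per group.

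Probe sets were assigned to genes with the platform's annotation and a RefSeq annotation of the mouse genome (GRCm38.p6), which gave names and chromosomes only. Of the probe sets, 64 were array controls, 34945 carried 1 gene symbol, 932 carried several and 9160 carried none. The 34945 covered 18193 genes, 9010 of them with more than 1 probe set, and each gene was represented by its probe set with the highest mean over all arrays. Values were returned to the signal scale, an offset of 9.70 signal units was added (the median over arrays of the 20th percentile) and log2 was taken again. A gene was tested where all 3 arrays of at least 1 compared line or group lay above the 40th percentile of their array.

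Differences were tested with limma 3.58.1 (statmod 1.5.0, R 4.3.3), with a mean-variance trend and robust empirical Bayes moderation. For ahES minus diploid ES, the 15 ES arrays were fitted with the cell line as a random block, whose consensus correlation was 0.687. For ahES minus MEF and ahES minus round sperm, a mean per group was fitted over all 21 arrays and the mean of the 3 ahES lines was compared with the other group. Pairs of lines of the same kind were compared over the 15 ES arrays. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold. All tests were 2-sided. Errors of differences are standard errors (SE), and errors of group means are standard deviations (SD) over arrays. Where the mean of a group lay at or below the mean of the 40th percentiles of its arrays (near background), the fold is given as a lower bound, computed with that percentile in place of the lower values.

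Lists of genes for cell types, imprinting, the germline, the cell cycle, stress responses and metabolism, 32 in all, were fixed before the data were examined, as were the comparisons, the thresholds and the rule for naming genes. Lists were tested with cameraPR, with a preset inter-gene correlation of 0.01, and adjusted over the lists tested in a comparison. The tests were repeated with a correlation estimated from residuals around the mean of each line or group. That repeat also took p from a t distribution with the residual degrees of freedom in place of a normal one. Its p-values thus reflect both changes. The estimate does not cover genes of a list that move together between lines. The tests were also repeated with fry, which asks whether the genes of a list move on balance in one direction without comparing them with other genes. Tests of the fixed lists between lines of the same kind, and tests of Hox genes and of interferon-responsive genes, were added after the data were examined. Genes were named by rule: in each of the 3 comparisons of ahES cells, the 12 largest rises and 12 largest falls among genes that passed and whose ranges over arrays did not overlap, in each list up to 4 members with the smallest adjusted p and any set of 5 or fewer members that passed, in each pair of lines the 3 largest rises and falls, and a set of key genes. Among the key genes, H19, Ddx3y, Ccnb1 and Gapdh had no probe set with a single symbol and were not used here. Genes named outside the rule are identified as such where they appear.

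The X chromosome was compared with the autosomes by the median difference per gene, by cameraPR, by Fisher's exact test on the genes that passed, and by an exact permutation of the 5 ES lines. Similarity of arrays was the Pearson correlation across 15379 genes, and genes are not independent replicates. RNA quality was read from the 3' and 5' control probe sets of Actb and Gapdh.

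The workflow was tested on simulated data with known changes. In the ahES minus diploid ES design, with spread as the model assumes, 29.9% of simulated 2-fold changes and 93.8% of 4-fold changes passed, with 11 false calls. With spread between lines drawn gene by gene, 64 genes were called falsely in that design, and 1 when each line was reduced to 1 mean, at which 54.7% of 4-fold changes passed. Of the genes at an adjusted p under 0.05 there, with no fold limit, 11.9% were false with spread as the model assumes. With spread drawn gene by gene, 52.2% were false, and 4.08% with 1 mean per line. In the ahES minus MEF and ahES minus round sperm designs, spread between lines drawn gene by gene gave 515 false calls each, against 2 and 4 without it. At an adjusted p under 0.05 with no fold limit, 94.5% and 94.6% of the genes were false there, against 4.26% and 4.09% without it. The adjusted p of the main fits thus did not hold its nominal rate where lines differed gene by gene. These shares depend on the number of changed genes, which was 62 to 67 at each simulated fold in the comparisons of ahES cells.

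Alternatives fixed in advance changed the offset (none or 19.4 signal units), the filter (none or the 60th percentile), the scaling (quantile normalization or median-centred arrays), the probe sets per gene, the moderation, the fold limit (none, or limma's treat at 1.5-fold), the treatment of lines (fixed, averaged or ignored) and the arrays and lines used. Alternatives without X-linked genes or without chromosome 8 genes, and some with arrays or lines left out, were added after the data were examined.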

Results

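The 21 arrays covered haploid and diploid pluripotent cells, fibroblasts and male germ cells of the mouse. Androgenetic haploid ES cells carry a single set of chromosomes of paternal origin and were represented by 9 arrays of 3 lines. Diploid ES cells were represented by 6 arrays of 2 lines, and MEF and round sperm, the haploid germ cells that follow meiosis, by 3 arrays each. Per the series description, the purpose was to compare the expression patterns of these kinds of cell. Across 15379 genes, arrays of 1 group had a mean Pearson correlation of 0.981 ± 0.004 (SD over 21 pairs of arrays). The mean correlation was 0.971 between ahES lines, 0.960 between the diploid ES lines, 0.954 between ahES and diploid ES arrays, 0.807 between ahES and MEF arrays and 0.255 between ahES and round sperm arrays. All 21 arrays were nearest to an array of their own group. These correlations are across genes, which are not independent replicates.

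RNA quality differed for round sperm. The Actb 3' minus 5' log2 difference was 0.55 ± 0.07 (SD, n = 9) in ahES, 0.57 ± 0.05 (n = 6) in diploid ES, 0.34 ± 0.06 (n = 3) in MEF and 0.74 ± 0.25 (n = 3) in round sperm. The Gapdh difference was -0.24 in both kinds of ES cell, -0.21 in MEF and 0.55 ± 0.17 (SD, n = 3) in round sperm. The poly-A spike control probe sets were also lower and more variable in round sperm. Their mean log2 signal was 7.24 ± 0.83 (SD, n = 3) there, from 6.42 to 8.09. It was 8.25 in ahES, 8.31 in diploid ES and 8.25 in MEF, and the cause was not tested.

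Whether haploid ES cells differ from diploid ES cells was the question of the comparison ahES minus diploid ES. The transcription factors at the centre of pluripotency did not pass in it: Pou5f1 differed by 0.02 ± 0.09 (log2 difference ± SE), Nanog by -0.08 ± 0.10 and Sox2 by -0.02 ± 0.14, with means of 13.6, 13.7 and 13.2 in ahES arrays (n = 9) and 13.6, 13.8 and 13.2 in diploid ES arrays (n = 6). Klf4, another pluripotency factor, differed by -0.51 ± 0.11 with an adjusted p of 0.00423, short of 2-fold. Of 28 tested genes of the pluripotency list, 1 was higher and 27 did not pass. The higher gene was Lefty1, an inhibitor of Nodal signalling, at 3.36-fold (log2 1.75 ± 0.25, 10.4 ± 0.39 against 8.66 ± 0.23, SD). The list had a mean difference of 0.10 and a median of -0.02, which was 0.02 with median-centred arrays, and its test gave an adjusted p of 0.882. Over all genes, 561 of 12891 passed, 387 higher and 174 lower in ahES cells, and in 501 of the 561 the ranges over arrays did not overlap.

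Of the 387 higher genes, 168 lay on the X chromosome. Gm364, an X-linked gene, was 183-fold higher in ahES cells (log2 7.52 ± 0.33, 13.9 ± 0.21 in 9 arrays against 6.34 ± 0.61 in 6, adjusted p = 2.35e-10). Magea5 was at least 54.0-fold higher and Magea6 at least 6.87-fold higher, both X-linked members of the MAGE family, which is best known from testis and tumours. Magea5 was near background in diploid ES cells and lowest in CS1-1 replicate 2, at 3.80, without which its log2 difference was 5.90 against 6.15. Efhc2, also on the X chromosome, was 27.1-fold higher (log2 4.76 ± 0.20). Of 454 tested X-linked genes, 168 (37.0%) were higher, against 217 of 12383 autosomal genes (1.75%), with an odds ratio of 32.9 (Fisher's exact test, p = 1.48e-148). No X-linked gene was lower by limma at the threshold; at an unadjusted p under 0.05, 331 were higher and 1 was lower. The median difference was 0.90 for X-linked and -0.04 for autosomal genes, a gap of 0.945 or 1.93-fold, and 94.9% of X-linked genes lay above 0 against 44.9% of autosomal genes. Each of the 6 pairs of an ahES and a diploid ES line showed it, with gaps of 0.869 to 1.05, while gaps within a kind lay between -0.12 and 0.003. Tested as a list with cameraPR, X-linked genes gave p = 2.04e-83, and p = 7.32e-13 with an estimated correlation. That estimate was 0, so the larger p came from the t distribution used with it. An exact 2-sided permutation of the 5 lines gave p = 0.1, the smallest that its 10 splits allow. Rlim, the X-linked activator of Xist, was 2.28-fold higher (log2 1.19 ± 0.16), and Xist itself, the RNA that silences an X chromosome, differed by 0.34 ± 0.36 and did not pass (adjusted p = 0.659), although without R1 it differed by 1.26 and passed.

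**Figure D1:**
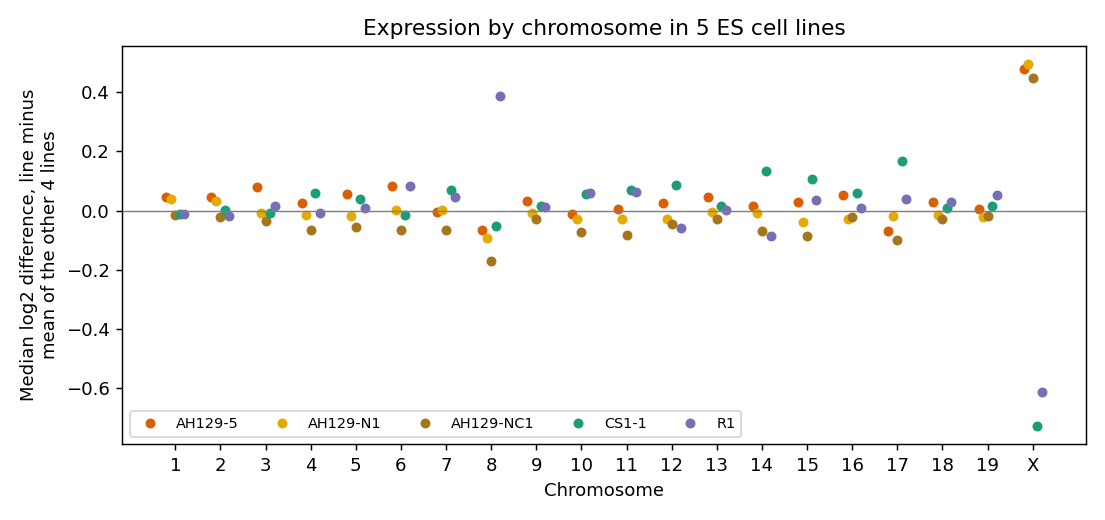
Median log2 difference of the genes of each chromosome (x axis, chromosomes 1 to 19 and X) between 1 ES line and the mean of the other 4 lines (y axis), with a point for each of the 5 lines. The ahES lines lie above and the diploid ES lines below 0 on the X chromosome, and R1 lies at 0.386 on chromosome 8.

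Outside the X chromosome, the largest rises included Cd3d, a chain of the T cell receptor complex, at least 29.6-fold higher (log2 5.60 ± 0.74, 10.5 ± 0.54 against 4.91 ± 0.88, near background), Hoxa9, a transcription factor of body axis patterning, at 16.9-fold (log2 4.07 ± 0.43), and Adgrg6, an adhesion receptor, at 12.7-fold (log2 3.67 ± 0.39). Among the largest falls were Epas1, the hypoxia-inducible factor HIF2A, at 6.30-fold (log2 -2.65 ± 0.33, 8.52 ± 0.84 against 11.2 ± 0.14), Cavin1, a coat protein of caveolae (log2 -2.59 ± 0.30), and Calb2, a calcium-binding protein, at 5.36-fold (log2 -2.42 ± 0.58). As the mean over its probe sets, Cavin1 differed by -1.03 and did not pass (adjusted p = 0.104), and without R1 Calb2 differed by -1.74 and did not pass (adjusted p = 0.0761).

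Imprinted genes were compared because androgenetic cells hold paternal chromosomes only. Of 22 tested paternally expressed genes, 21 had a positive difference, 3 were higher, 1 was lower and 18 did not pass, and the count adjusted over the list alone was 4 higher and 1 lower. The higher genes were Ndn, a growth suppressor, at 3.74-fold (log2 1.90 ± 0.28), Sfmbt2, a polycomb protein, at 2.73-fold (log2 1.45 ± 0.26), and Impact, a translational regulator, at 2.14-fold (log2 1.09 ± 0.11). The lower gene was Slc38a4, an amino acid transporter (log2 -1.08 ± 0.24). The list was higher in ahES cells by a mean of 0.52, its mean lay higher in each of 9 ahES arrays than in any of 6 diploid ES arrays, and its test gave an adjusted p of 8.67e-04, and an adjusted p of 0.0588 with an estimated correlation. Of 32 tested maternally expressed genes, 1 was higher, 1 was lower and 30 did not pass, with a mean of -0.14 and an adjusted p of 0.274. The lower gene was Phlda2, a brake on placental growth, at 3.73-fold (log2 -1.90 ± 0.45), and the higher was Dcn, a matrix proteoglycan that also belonged to the fibroblast list (log2 2.08 ± 0.61). The Dcn call ended without any 1 of 11 of the 15 arrays, namely the 9 ahES arrays and CS1-1 replicates 1 and 2 (adjusted p of 0.0503 to 0.0590), and Dcn differed by 0.48 without CS1-1. Igf2, Igf2r, Meg3 and Cdkn1c did not pass, at 0.66 ± 0.48, 0.07 ± 0.21, -0.39 ± 0.16 and -0.21 ± 0.53, although Igf2 differed by 1.86 and passed without R1. Igf2 was far higher in MEF than in ahES cells, and the fibroblast list had a mean of 1.81 against CS1-1. Whether the Igf2 difference belongs to imprinting or to the fibroblast signal was not tested. As the mean over its probe sets, Impact differed by 0.24 and did not pass.

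Germline genes that are normally silenced by DNA methylation were higher in ahES cells. Of 23 tested, 8 were higher, 1 was lower and 14 did not pass, and the count adjusted over the list alone was 8 higher and 2 lower. Tex13b rose 8.37-fold (log2 3.07 ± 0.48), the homeobox gene Rhox6 5.64-fold (log2 2.50 ± 0.35) and Taf7l, a testis form of a general transcription factor, 4.28-fold (log2 2.10 ± 0.35), all of them X-linked. The lower gene was Ddx4, a germ cell RNA helicase (log2 -1.17 ± 0.36), whose call ended without any 1 of the 3 CS1-1 arrays (adjusted p of 0.0513 to 0.0542). The list's adjusted p was 2.01e-04, and 0.0254 with an estimated correlation, and without X-linked genes it was 0.0349 with 3 of 17 genes higher and 1 lower. Of 14 genes of the primed epiblast, the state that follows naive pluripotency, 5 were higher and 9 did not pass (mean 0.48, adjusted p = 0.0111, and adjusted p = 0.0766 with an estimated correlation). They included the de novo DNA methyltransferases Dnmt3b at 2.39-fold (log2 1.26 ± 0.15) and Dnmt3a at 2.33-fold (log2 1.22 ± 0.25), and Zic2, Sox3 and Lefty2. The DNA methylation list as a whole had 2 of 17 genes higher, a mean of 0.06 and a median of -0.09 (adjusted p = 0.878). Of 15 trophoblast genes, 3 were higher, 1 was lower and 11 did not pass, with 4 higher and 1 lower adjusted over the list alone (adjusted p = 0.101). Cdx2, the transcription factor of the trophectoderm, was 12.2-fold higher (log2 3.61 ± 0.31, 9.74 ± 0.42 against 6.13 ± 0.42), Fgfr2, a growth factor receptor, 3.29-fold (log2 1.72 ± 0.33) and Plac1, a placental gene near background in diploid ES cells, at least 2.57-fold, and Eomes, a T-box factor, was lower (log2 -1.17 ± 0.35). Fgfr2 differed by 0.78 and did not pass as the mean over its probe sets (adjusted p = 0.113), nor without the probe sets whose names end in _x_at or _s_at (0.78, adjusted p = 0.273). Plac1 did not pass without AH129-5 (1.57, adjusted p = 0.106) or CS1-1 (1.72, adjusted p = 0.0627), nor Eomes without AH129-N1 (-0.93, adjusted p = 0.106) or CS1-1 (-0.95, adjusted p = 0.211) or with the filter at the 60th percentile (adjusted p = 0.0718).

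Cell cycle and sterol genes were lower in ahES cells as lists. The S phase list had a mean of -0.25 over 38 genes (adjusted p = 1.15e-05, and adjusted p = 0.0766 with an estimated correlation), and the G2/M list a mean of -0.21 over 39 genes (adjusted p = 8.67e-04, and adjusted p = 0.168 with an estimated correlation). No gene of either list passed in limma; at an unadjusted p under 0.05, 15 S phase genes were lower, and 16 G2/M genes were lower and 1 was higher, and fry gave adjusted p of 3.3e-04 and 0.00887. The ahES cells had been sorted in G0/G1 and no sort was stated for the diploid ES cells. Of 20 cholesterol synthesis genes, 4 were lower, 1 was higher and 15 did not pass (mean -0.43, adjusted p = 4.44e-04, and adjusted p = 0.0774 with an estimated correlation). The sterol enzymes Tm7sf2, Msmo1, Fdft1 and Dhcr7 fell by 1.48, 1.09, 1.09 and 1.07 on the log2 scale, and Ebp, a sterol isomerase encoded on the X chromosome, rose 3.08-fold (log2 1.62 ± 0.10). Of 30 immediate early genes, 3 were lower, 1 was higher and 26 did not pass (adjusted p = 0.101), with 1 higher and 4 lower adjusted over the list alone. The list mean was 0.21 against CS1-1 and -0.77 against R1. Fos fell by 2.22 ± 0.20, Egr2 by 2.14 ± 0.50 and Egr1 by 1.23 ± 0.24, all growth factor-induced transcription factors, and Ier5 rose by 1.30 ± 0.26.

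Fibroblast genes were tested as markers of another cell type. Of 38, 2 were higher in ahES cells, Dcn and Lum (log2 1.47 ± 0.44), 1 was lower, Tgfbi (log2 -1.01 ± 0.25, and short of 2-fold without AH129-N1 replicate 1 or CS1-1 replicate 1), and 35 did not pass (mean 0.65, adjusted p = 0.0160, and adjusted p = 0.275 with an estimated correlation). The direction depended on the diploid line, with a list mean of 1.81 against CS1-1 and -0.51 against R1. The labels state no feeder layer for any ES line, so whether this signal came from feeder cells or from the ES cells is not known. The median fibroblast gene stood at 7.71%, 5.41% and 5.98% of its MEF signal in AH129-5, AH129-N1 and AH129-NC1, at 1.23% in CS1-1 and at 8.71% in R1. The genes differed widely in this share. In AH129-5, AH129-N1 and AH129-NC1 it ran from 0.79% to 161%, 0.38% to 163% and 1.01% to 120%, with lower quartiles of 3.15%, 2.23% and 2.92%. It ran from 0.09% to 196% in CS1-1 and from 1.81% to 95.2% in R1. No single share of RNA like that of these MEF accounts for all of the genes. Ndn, whose MEF level was 12.98, was at 10.34, 10.27 and 10.51 in the ahES lines, 7.64 in CS1-1 and 9.29 in R1. The Sertoli cell list (10 genes, 1 higher, the X-linked homeobox gene Rhox5, mean 0.42, adjusted p = 0.0167) and the list of the unfolded protein and integrated stress responses (29 genes, 2 higher, mean 0.23, adjusted p = 0.0425) also passed, with adjusted p = 0.137 and 0.0932 with an estimated correlation. Without Rhox5, its X-linked gene, the Sertoli cell list did not pass (9 genes, mean 0.33, adjusted p = 0.0544). The 2 stress genes were Chac1, which degrades glutathione (log2 1.41 ± 0.36), and Aldh1l2, a mitochondrial folate enzyme (log2 1.13 ± 0.30). In total 9 of 32 lists passed, 6 higher and 3 lower, and of these only the germline list passed with an estimated correlation. That estimate came from arrays within lines, so it does not test whether a list moves together between the 5 lines. Among the lists that did not pass were p53 targets (27 genes, mean -0.27, adjusted p = 0.274), Y-linked genes (4 genes, mean -1.25, adjusted p = 0.290) and meiosis genes, whose mean of 0.02 and median of -0.21 differed in sign and of which Syce1 was higher.

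Only 2 diploid ES lines stand behind this comparison. With 1 mean per line, 284 genes passed, 269 of them shared with the 561, and of the 63 named genes that passed, 29 no longer did, among them Epas1, Ndn, Sfmbt2, Slc38a4, Phlda2, Dcn, Lum, Tgfbi, Dnmt3a, Zic2, Sox3, Lefty2, Plac1, Eomes, Tex13b, Ddx4, Syce1, Egr1, Egr2, Ier5, Chac1, Aldh1l2, Tm7sf2, Fdft1 and Dhcr7. Without R1, 1098 genes passed, 483 of them shared, and 13 of the 63 named genes no longer did, among them Phlda2 (-0.79), Egr2 (-1.31), Egr1 (-0.71), Chac1 (0.65), Impact (0.81), Rhox5 (0.93) and Dhcr7 (-1.09). Without CS1-1, 22 of 62 no longer passed, among them Lum (0.54), Ddx4 (-0.46), Aldh1l2 (0.65), Ier5 (0.75), Slc38a4 (-0.75), Syce1 (0.77), Tgfbi (-0.71), Tm7sf2 (-0.99), Msmo1 (-0.99), Sox3 (1.11) and Dhcr7 (-1.06). Without an ahES line, 10 to 12 of 63 no longer passed, Chac1, Aldh1l2, Dhcr7, Fdft1, Msmo1, Rlim and Sox3 among them without AH129-5, Dcn, Ddx4, Lum, Phlda2, Slc38a4 and Tgfbi without AH129-N1, and Dcn, Ddx4, Dhcr7, Lum, Phlda2 and Tgfbi without AH129-NC1. As the mean over the probe sets of a gene, 12 of 61 no longer passed, among them Dcn (0.94), Sfmbt2 (0.99), Sox3 (0.68), Fdft1 (-0.56), Msmo1 (-0.98), Tgfbi (-0.92) and Ier5 (0.52).

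**Figure D2:**
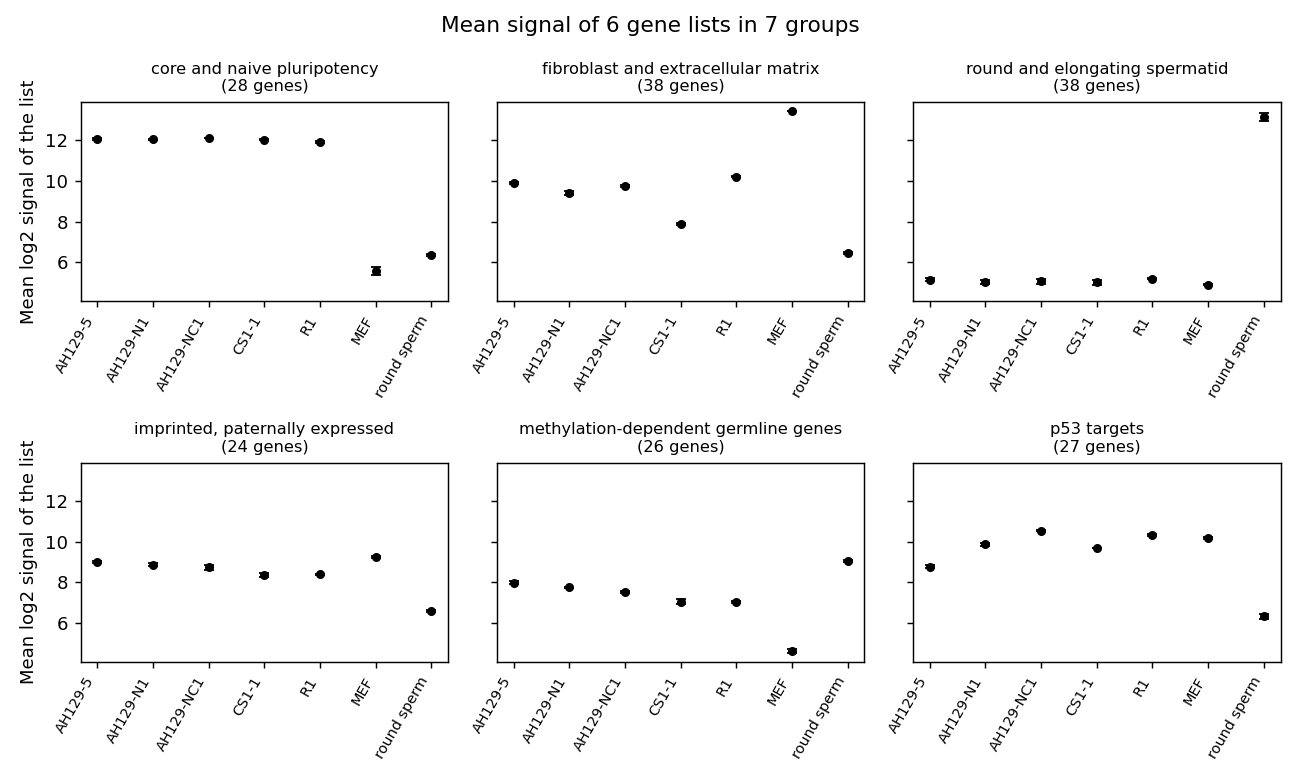
Mean log2 signal of the genes of 6 fixed lists (y axis, a panel for each list) in the 7 groups (x axis), as points with SD over 3 arrays. Fibroblast genes stand highest in MEF and spermatid genes highest in round sperm.

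How ahES cells differ from a somatic cell was asked in ahES minus MEF. The pluripotency genes were far higher in ahES cells: Nanog rose at least 314-fold, Pou5f1 at least 294-fold and Zfp42, a naive pluripotency marker, at least 265-fold, all near background in MEF. Sox2 rose 81.3-fold (log2 6.34 ± 0.15, 13.2 ± 0.22 in 9 arrays against 6.82 ± 0.28 in 3), and Klf4, which fibroblasts also express, rose 3.68-fold (log2 1.88 ± 0.06). All 28 tested pluripotency genes were higher (mean 6.52, adjusted p = 1.07e-15, and adjusted p = 3.5e-04 with an estimated correlation). The largest rise was that of Trap1a, an X-linked gene, at least 402-fold. Of 38 fibroblast and matrix genes, 35 were lower and 3 did not pass (mean -3.74, adjusted p = 5.09e-16, and adjusted p = 7.92e-05 with an estimated correlation). Among the largest falls were Tm4sf1, a membrane protein near background in ahES cells, at least 249-fold (log2 -8.33 ± 0.35), the contractile genes Myl9 at 123-fold (log2 -6.94 ± 0.26) and Tagln at 105-fold (log2 -6.72 ± 0.20), and S100a4, a calcium-binding protein of mesenchymal cells, at 122-fold (log2 -6.93 ± 0.20). Collagen genes fell less, Col1a1 10.6-fold (log2 -3.40 ± 0.14) and Col1a2 4.11-fold (log2 -2.04 ± 0.13).

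Germline, replication and methylation genes were also higher in ahES cells than in MEF. Of 22 methylation-dependent germline genes, 18 were higher and 1 lower, the tudor domain gene Tdrkh (mean 3.54, adjusted p = 5.25e-07), Dazl, an RNA-binding protein of germ cells, at least 46.4-fold. Of 18 meiosis genes, 16 were higher and 2 did not pass (mean 3.04, adjusted p = 5.25e-07), Sycp3, a part of the synaptonemal complex, at least 12.2-fold. Of 17 spermatogonial genes, 11 were higher and 2 lower, Gfra1 and Rarg (mean 2.38, adjusted p = 0.00839), and of 15 primed epiblast genes, 11 were higher and 2 lower, Fgf5 and Sall2 (mean 2.37, adjusted p = 0.00439). Of 38 S phase genes, 26 were higher and 12 did not pass (mean 1.41, adjusted p = 6.14e-10), the replication factors Gins1 6.32-fold and Mcm5 4.45-fold. Of 39 G2/M genes, 17 were higher (mean 0.85, adjusted p = 5.85e-07, and adjusted p = 0.0808 with an estimated correlation). Tet1, a methylcytosine dioxygenase, rose 57.6-fold, Dnmt3b 40.5-fold and Dnmt3l 13.9-fold, and 8 of 17 DNA methylation genes were higher and 3 lower (adjusted p = 0.0206). Of 30 polycomb and histone modifier genes, 14 were higher and 1 lower (mean 1.30, adjusted p = 4.69e-05, and adjusted p = 0.0703 with an estimated correlation). Oxidative phosphorylation genes had a mean of 0.30 (adjusted p = 0.00318, and adjusted p = 0.294 with an estimated correlation). None of 35 passed in limma, 28 were higher and 2 lower at an unadjusted p under 0.05, and fry gave an adjusted p of 1.12e-08.

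Lists lower in ahES cells than in MEF were cholesterol synthesis, with 7 of 20 genes lower and 1 higher (mean -0.92, adjusted p = 5.68e-05), Leydig and peritubular cells, with 7 of 11 lower and 1 higher (mean -3.10, adjusted p = 0.00318, and adjusted p = 0.0572 with an estimated correlation), and primitive endoderm, with 9 of 13 lower and 2 higher (mean -1.81, adjusted p = 0.0217, and adjusted p = 0.0808 with an estimated correlation). Imprinted genes went both ways. Of 23 paternally expressed genes, 6 were higher and 8 lower (adjusted p = 0.415), and of 35 maternally expressed genes, 6 were higher and 16 lower (adjusted p = 0.0657). Igf2, a fetal growth factor, fell 20.4-fold (log2 -4.35 ± 0.12), Cdkn1c, an inhibitor of the cell cycle, 12.2-fold (log2 -3.61 ± 0.28) and Grb10, a growth-inhibiting adaptor, 10.2-fold (log2 -3.35 ± 0.07), while Sfmbt2 rose 9.70-fold (log2 3.28 ± 0.09). Meg3 differed by -0.04 ± 0.09 and did not pass, but as the mean over its probe sets it was lower, at -1.24. Xist was 9.78-fold lower (9.47 ± 0.37 against 12.8 ± 0.07). In total 5568 of 13220 genes passed, 2788 higher and 2780 lower, and 14 of 32 lists passed, 9 of them with an estimated correlation. MEF were 1 group of CD1 mice against the 129 Sv background of the ES cells, so strain and kind of cell are not separated. The test judged differences against the spread between arrays within groups. Median-centred arrays moved the median of all genes to 0.20.

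How ahES cells differ from the haploid male germ cell was asked in ahES minus round sperm. The protamines and transition proteins, which replace histones in sperm chromatin, were far lower in ahES cells: Prm1 was at least 777-fold lower (log2 -10.7 ± 0.32, 4.45 ± 0.60 in 9 arrays against 15.1 ± 0.24 in 3), Prm2 at least 861-fold lower, Tnp2 at least 729-fold lower and Tnp1 at least 19-fold lower. Hils1, a spermatid linker histone, was at least 626-fold lower, and the ahES means of all 5 genes were near background. Of 38 spermatid genes, 36 were lower and 2 did not pass (mean -8.04, adjusted p = 5.2e-11, and adjusted p = 5.84e-04 with an estimated correlation). Of 27 meiosis genes, 22 were lower and 5 did not pass (mean -3.58, adjusted p = 4.01e-06, and adjusted p = 9.75e-04 with an estimated correlation), Ldhc, a testis lactate dehydrogenase, 345-fold. All 5 tested Y-linked genes were lower (mean -4.04, adjusted p = 0.0253, and adjusted p = 0.0621 with an estimated correlation), with Eif2s3y, a translation factor, at 5.43 in ahES cells, near background, and 10.5 in round sperm.

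Pluripotency genes were higher in ahES cells than in round sperm, 25 of 28, and 3 did not pass (mean 5.73, adjusted p = 3.15e-06). Nanog rose at least 301-fold, Sox2 at least 202-fold and Pou5f1 86.0-fold, whereas Klf4 differed by 0.12 ± 0.06 and did not pass, at 13.3 in ahES cells and 13.2 in round sperm. Replication genes were higher as well, 30 of 38 S phase genes with 1 lower, Rfc2 (mean 2.99, adjusted p = 3.15e-06), Mcm4 84.3-fold. Of 26 p53 targets, 23 were higher (mean 3.48, adjusted p = 1.05e-04), Ccng1 at least 115-fold and Cdkn1a 43.9-fold. Fibroblast and matrix genes were higher, 32 of 38 with 2 lower, Loxl1 and Snai2 (mean 3.21, adjusted p = 2.2e-04), and Col1a2 75.1-fold. Immediate early genes (24 of 30 higher, 2 lower, adjusted p = 0.00179), stress response genes (20 of 30 higher, 3 lower, adjusted p = 0.00241) and DNA methylation genes (13 of 17 higher, adjusted p = 0.0158) also passed, with Dnmt3b up 57.8-fold and Dnmt3l differing by 0.07 ± 0.13. Of 23 paternally expressed imprinted genes, 18 were higher and 1 lower, Rasgrf1 (mean 2.35, adjusted p = 0.0165, and adjusted p = 0.0328 with an estimated correlation), the zinc finger genes Plagl1 at least 410.0-fold and Peg3 49.9-fold. Of 34 maternally expressed genes, 15 were higher and 10 lower (adjusted p = 0.952), Meg3 45.8-fold higher and Cdkn1c 13.5-fold lower. X-linked genes had a median difference of 2.85.

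Lists that passed against round sperm with the preset correlation and lost it with an estimated one were Y-linked genes (adjusted p = 0.0621 with an estimated correlation), primed epiblast (12 of 14 higher, 1 lower, adjusted p = 0.0667 with an estimated correlation), glycolysis (16 of 24 higher, 2 lower, adjusted p = 0.102 with an estimated correlation), cholesterol synthesis (14 of 20 higher, 1 lower, adjusted p = 0.161 with an estimated correlation and 0.0705 without X-linked genes), polycomb and histone modifiers (19 of 30 higher, 3 lower, adjusted p = 0.208 with an estimated correlation) and housekeeping genes (9 of 15 higher, 1 lower, adjusted p = 0.331 with an estimated correlation). In total 10774 of 14765 genes passed, 6025 higher and 4749 lower, and 16 of 32 lists passed, 10 of them with an estimated correlation. The median difference of all genes was 0.33 as deposited, 0.10 with quantile normalization, which gave 5508 higher and 5235 lower, and -0.19 with median-centred arrays, which gave 4982 higher and 5724 lower, so the split between higher and lower depends on scaling. Round sperm also differed in RNA quality and in the signal of the poly-A spike controls, and had 3 arrays.

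Lines of the same kind were compared to show how far they differ among themselves. AH129-5 differed from both other ahES lines in the targets of p53, the transcription factor of the DNA damage response. Of 26 tested, 13 were lower and 1 higher in AH129-5 than in AH129-N1 (mean -1.14, adjusted p = 5.89e-15, and adjusted p = 0.00304 with an estimated correlation), and 20 were lower than in AH129-NC1 (mean -1.80, adjusted p = 1.29e-30, and adjusted p = 1.38e-04 with an estimated correlation). The targets lower in both pairs numbered 13. Eda2r, a receptor of the tumour necrosis factor family, was 30.3-fold lower in AH129-5 than in AH129-N1 (log2 -4.92 ± 0.09, 6.33 ± 0.15 against 11.3 ± 0.12, n = 3 each) and 48.6-fold lower than in AH129-NC1. Cdkn1a, which arrests the cell cycle, was lower by log2 -1.86 and -2.55, and Ccng1 and Psrc1, chosen after their values were seen, by -2.56 and -3.29 and by -2.76 and -3.47. AH129-N1 was lower than AH129-NC1 in 2 of 26 targets (mean -0.67, adjusted p = 1.12e-14, and adjusted p = 0.00328 with an estimated correlation).

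**Figure D3:**
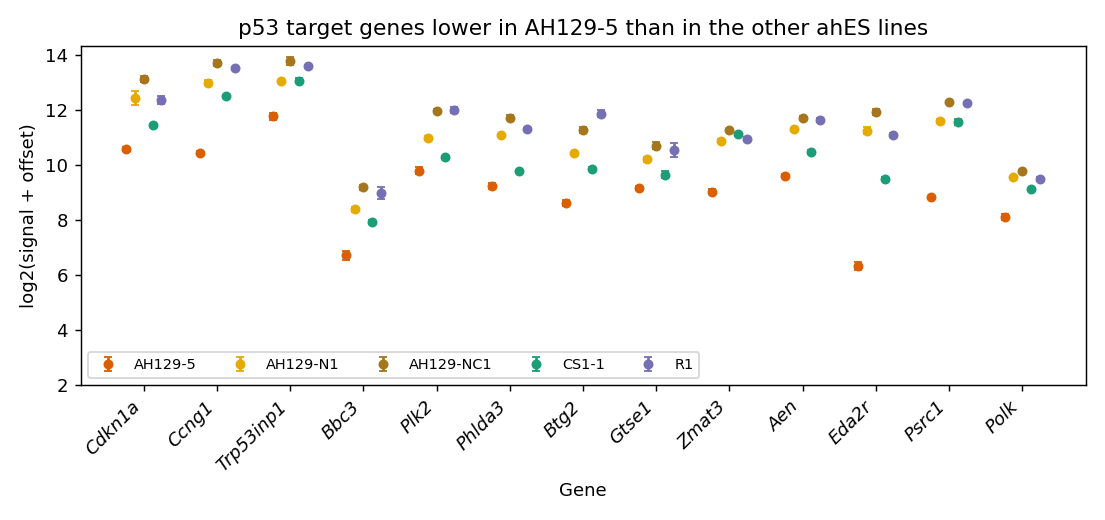
Mean log2 of signal plus offset (y axis) of the 13 p53 targets that were lower in AH129-5 than in both other ahES lines (x axis), with a point for each of the 5 ES lines and SD over 3 arrays. AH129-5 stands lowest of the ahES lines at each gene, as the selection of the genes requires, and also below CS1-1 and R1.

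Other genes that set the ahES lines apart were Ripply3, a transcriptional repressor, at least 6.53-fold higher in AH129-5 than in AH129-N1, Krt18, an epithelial keratin, 8.57-fold higher in AH129-5 than in AH129-NC1, Dppa3, a maternal factor that protects DNA methylation, 5.22-fold higher in AH129-N1 than in AH129-NC1 (log2 2.38 ± 0.07), and Irgm1, an interferon-inducible GTPase, 7.86-fold lower in AH129-N1 than in AH129-NC1. Glycolysis genes were higher in AH129-N1 than in AH129-NC1 as a list (24 genes, 2 of them past the threshold, mean 0.46, adjusted p = 4.02e-09, and adjusted p = 0.0381 with an estimated correlation). In all, 645 of 12149 genes differed between AH129-5 and AH129-N1 (468 higher, 177 lower), 655 of 12195 between AH129-5 and AH129-NC1 (393 higher, 262 lower) and 376 of 12077 between AH129-N1 and AH129-NC1 (118 higher, 258 lower). For AH129-5 against AH129-NC1 the split was 278 higher and 320 lower with quantile normalization, and 325 and 296 with median-centred arrays.

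The diploid lines CS1-1 and R1 differed in 1194 of 12100 genes, 505 higher and 689 lower in CS1-1. Eif2s3y was at least 66.1-fold lower in CS1-1 (4.23 ± 0.20 against 11.5 ± 0.03, n = 3 each), and all 3 tested Y-linked genes were lower (mean -4.53, adjusted p = 0.00327, and adjusted p = 0.0361 with an estimated correlation). In the ahES lines Eif2s3y stood at 5.21 to 5.69. Of 38 fibroblast genes, 31 were lower and 1 higher in CS1-1 (mean -2.32, adjusted p = 7.04e-22, and adjusted p = 0.00247 with an estimated correlation), Col1a2 10.3-fold and Col1a1 5.73-fold. Ccl2, a chemokine of fibroblasts and monocytes, was 21.9-fold lower. Immediate early genes (16 of 30 lower, mean -0.98, adjusted p = 0.0185 with an estimated correlation) and p53 targets (11 of 27 lower, 1 higher, mean -0.64, adjusted p = 0.0185 with an estimated correlation) were lower and glycolysis genes higher (8 of 25, mean 0.77, adjusted p = 0.0185 with an estimated correlation). The imprinted genes Igf2, Phlda2 and Grb10 were 5.29-fold, 4.61-fold and 2.57-fold lower in CS1-1 and Peg3 was 3.03-fold higher. Igf2 and Grb10 were also higher in MEF than in ahES cells, so their fall in CS1-1 is not separated from that of the fibroblast genes. As the mean over its probe sets, Grb10 differed by -0.83 against -1.36, short of 2-fold. Ubd, a ubiquitin-like protein, was at least 13.5-fold higher in CS1-1. Each line was represented by 3 arrays. The differences were judged against the spread between arrays within lines, pooled over the 5 ES lines.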

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

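The tests of array scaling and of a few strongly raised genes on the X chromosome, of fibroblast RNA and array scaling for p53 targets, and of a few strongly raised genes and ordinary spread for chromosome 8 were chosen after the results were seen, as were the list tests between lines and the splits of whole lines and groups for MEF and round sperm.

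X-linked genes were higher in ahES cells than in both diploid ES lines, with a gap between X-linked and autosomal medians of 0.945. Array scaling moves X-linked and autosomal genes of an array alike and could hardly make such a gap, so the test of scaling was all but settled in advance. The smallest gap over the 6 pairs of an ahES and a diploid ES line was 0.869, against at most 0.12 in size between lines of the same kind. A few strongly raised genes cannot move a median, so the test of that explanation was settled by the measure and adds no support. Of the X-linked genes that differed by under 4-fold, 95.9% lay above the autosomal median. A candidate explanation is dosage, with 1 X chromosome per set of autosomes in ahES cells and 1 active X chromosome per 2 sets in diploid ES cells, and the smallest median over 4 equal stretches of the X chromosome by gene order was 0.84, as this hypothesis needs. The number of X chromosomes in CS1-1 was not measured. Y-linked genes had a mean of 4.57 in CS1-1 and 7.38 in R1, so the lines differ in Y expression. The X chromosome gap of CS1-1 minus R1 was -0.12 all the same, which argues against a higher dose of active X chromosomes in CS1-1 than in R1. Xist was lower in CS1-1 than in ahES cells, by 1.26. Other differences between the kinds of cell, such as the paternal origin of the X chromosome, stay open and untested.

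The targets of p53 were lower in AH129-5 than in both other ahES lines, 13 of them in both. Less fibroblast RNA in AH129-5 is argued against by the fibroblast list, which moved in the other direction, by a mean of 0.48 against AH129-N1 (cameraPR adjusted p = 2.91e-05, which was 0.0736 with an estimated correlation, and fry adjusted p = 1.21e-06). Against AH129-NC1, where the targets fell most, its mean was 0.15 with 28 of 38 genes above 0, which did not pass in cameraPR (adjusted p = 0.270) and was higher in fry (adjusted p = 0.0044). Loss of 1 chromosome region that holds the targets is argued against by the 9 chromosomes on which the 13 targets lie. That count cannot address loss of a region that holds a regulator of the targets, such as p53 itself, and this was not tested. With quantile normalization the list mean was -1.20 in the pair closer to 0. Array scaling moves all genes of an array alike, so this test too was all but settled in advance and adds no support. Lower activity of p53 itself in AH129-5 may account for the pattern, but no measurement here tests it.

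Genes of chromosome 8 were higher in R1 than in the other 4 ES lines, with a median of 0.386 over 682 genes. Of these genes, 83.7% lay above 0, but a median cannot be moved by a few strongly raised genes, so that test was settled by the measure. Ordinary spread between chromosomes is argued against by the largest absolute median of any other autosome in any line, 0.17 for chromosome 17 in CS1-1. An extra copy of chromosome 8 in R1 cells, or in a part of them, may account for it, and the smallest median over 4 equal stretches of the chromosome was 0.37, which is consistent with a change of the whole chromosome. No other biological explanation was tested, and DNA copy number was not measured.

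A single array stood far from the others of its kind in 2 of 128 groups of values examined. The arrays of a kind were pooled over lines, whose differences widen the range and can hide a single array. The groups of values also share arrays, so the count cannot be set against a chance rate. Padi2 stood at 4.44 in AH129-N1 replicate 1 among the ahES arrays, and Magea5 at 3.80 in CS1-1 replicate 2 among the diploid ES arrays.

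Of the 8 lists that passed in CS1-1 minus R1, 5 also passed with an estimated correlation, and in these 5 ahES minus CS1-1 and ahES minus R1 had opposite signs. The means were 0.51 and -4.02 for Y-linked genes (a difference of 4.53), 1.81 and -0.51 for fibroblast genes (2.32), 0.05 and -0.59 for p53 targets (0.64), 0.21 and -0.77 for immediate early genes (0.98) and -0.52 and 0.25 for glycolysis genes (-0.77). The higher mean of fibroblast genes in ahES minus diploid ES thus held against CS1-1 alone. Each was tested as CS1-1 minus R1. Over its 5 genes the Y-linked list lay near background in the ahES lines, at 4.81 to 4.89, and in CS1-1, at 4.57. Its 0.51 is therefore no evidence of Y-linked expression in ahES cells. The 0.05 of the p53 targets is too small to be read as a rise.

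Among 10092 probe sets without a single gene symbol, which the comparisons of genes did not use, 3985 were tested in ahES minus diploid ES and 172 passed, 106 higher and 66 lower.

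Other splits of the samples were counted for each comparison. The 10 splits of the 5 lines are too few for a share under 0.05 in ahES minus diploid ES (561, highest other 51). The same is true of the 4 splits of the 3 ahES lines and the other group in ahES minus MEF (5568, highest other 1804) and in ahES minus round sperm (10774, highest other 5347), where 100 splits of single arrays, which treat arrays of a line as independent, gave at most 1199 and 5389 genes apart from the real split. It is also true of the pairs of lines, each with 10 splits: AH129-5 minus AH129-N1 (645, highest other 0), AH129-5 minus AH129-NC1 (655, highest other 0), AH129-N1 minus AH129-NC1 (376, highest other 1) and CS1-1 minus R1 (1194, highest other 0).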

How the results depend on the processing

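The alternatives without X-linked genes or chromosome 8 genes, those of the list means and the X chromosome gap without 1 array, and those of the count of lists without 1 line, were chosen after the data were seen. The X chromosome gap, the pluripotency list and the maternally expressed list kept their direction and side of the threshold in each alternative run for them, with ranges of 0.777 to 1.01, 0.05 to 0.15 and -0.27 to -0.03. So did the paternally expressed and G2/M lists (0.35 to 0.62 and -0.27 to -0.16) apart from the estimated correlation, which left their means at 0.52 (adjusted p = 0.0588) and -0.21 (adjusted p = 0.168).

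The count of 561 genes in ahES minus diploid ES moved with the treatment of lines and the fold limit. It was 1505 with no fold limit, 188 with treat at 1.5-fold (186 shared), 1030 with lines as fixed effects, 953 with arrays as independent, 284 with 1 mean per line, and 481 (without AH129-NC1) to 1098 (without R1) with 1 line left out. With X-linked genes left out it was 376. Of 32 lists, 1 passed there with an estimated correlation, 14 with fry, and 6 (without AH129-5) to 14 (without CS1-1) with 1 line left out, against 9. With an estimated correlation and with fry, 9 and 30 lists passed in ahES minus MEF and 10 and 31 in ahES minus round sperm.

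With no fold limit, which admits smaller changes by construction, 10167 genes passed in ahES minus MEF, 5187 in AH129-5 minus AH129-N1, 4796 in AH129-5 minus AH129-NC1, 4372 in AH129-N1 minus AH129-NC1 and 6016 in CS1-1 minus R1. With treat, 410, 394 and 153 genes passed in the 3 ahES pairs, in the same order. With the filter at the 60th percentile, which tests fewer genes, 420 passed in AH129-5 minus AH129-N1 and 219 in AH129-N1 minus AH129-NC1. Without a filter, the correlation with ahES arrays was 0.846 for MEF and 0.411 for round sperm. As the mean over probe sets, Eed differed by -0.68 in ahES minus round sperm, against 2.37, and Ddit3 by 0.11, against -2.01, and the cause was not tested, nor for the other moves given without one.

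With 1 array left out, the counts ran from 537 to 573 in ahES minus diploid ES, 5569 to 5606 in ahES minus MEF, 10766 to 10968 in ahES minus round sperm, 641 to 684, 627 to 665 and 357 to 418 in the ahES pairs and 1179 to 1224 in CS1-1 minus R1. The list means ran from 0.47 to 0.54 (paternally expressed), -0.16 to -0.10 (maternally expressed), -0.21 to -0.20 (G2/M) and 0.09 to 0.11 (pluripotency), and the X chromosome gap from 0.934 to 0.955. The replicate number as a block gave 524 genes in ahES minus diploid ES, 5570 against MEF and 10776 against round sperm. Of the named genes that passed, 44 of 63 in ahES minus diploid ES lost their call in at least 1 alternative, 23 of 173 against MEF and 22 of 206 against round sperm, Eed and Ddit3 included. Low signals near background limit folds, which are lower bounds for the genes concerned.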

Other observations

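The tests of Hox and interferon-responsive genes were chosen after the results were seen, and their p-values are not adjusted over lists.

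Hox genes, the transcription factors of body axis patterning, were higher in ahES than in diploid ES cells. All 19 tested had a positive difference, 4 were higher and 15 did not pass (mean 1.33, cameraPR p = 1.57e-07, and p = 1.99e-04 with an estimated correlation). Hoxa9 was 16.9-fold higher (log2 4.07 ± 0.43), Hoxa10 at least 8.85-fold (log2 3.65 ± 0.47), Hoxc9 at least 6.30-fold (log2 3.19 ± 0.63) and Hoxc8 3.29-fold (log2 1.72 ± 0.52), and apart from Hoxa9 these genes were chosen after their values were seen. Of 15 tested, 5 were lower in CS1-1 than in R1 (mean -0.96, p = 1.26e-04, and p = 0.00565 with an estimated correlation). The fibroblast list moved the same way there, at 7.88 in CS1-1, 9.42 to 9.90 in the ahES lines, 10.2 in R1 and 13.4 in MEF. The mean over 27 Hox genes was 5.23 in CS1-1, 6.0 in R1, 6.41 to 6.72 in the ahES lines and 7.72 in MEF, so that R1 stood above the ahES lines in fibroblast genes and below them in Hox genes. Against MEF, 12 of 26 were lower and 2 higher in ahES cells (mean -1.18, p = 0.00341, and p = 0.00884 with an estimated correlation).

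Interferon-responsive genes differed between ahES lines. Of 28 tested, 14 were higher in AH129-5 than in AH129-N1 (mean 1.14, p = 8.07e-11, and p = 2.53e-05 with an estimated correlation), and of 31 tested, 16 were lower in AH129-N1 than in AH129-NC1 (mean -1.10, p = 6.36e-15, and p = 4.64e-06 with an estimated correlation). AH129-5 and AH129-NC1 had 2 of 32 genes higher. The mean difference of that list was 0.06 (p = 0.855, and p = 0.839 with an estimated correlation). In CS1-1, 8 of 30 were lower than in R1 (mean -0.54, p = 1.23e-04, and p = 0.00366 with an estimated correlation). The fibroblast list was likewise lowest of the ahES lines in AH129-N1, at 9.42 against 9.90 in AH129-5 and 9.75 in AH129-NC1, and lower in CS1-1 than in R1, while the mean over 33 interferon-responsive genes was 7.19 in MEF, 6.95 in AH129-N1, 8.05 in AH129-5, 7.98 in AH129-NC1, 7.53 in CS1-1 and 8.11 in R1. Between ahES and diploid ES cells 2 of 32 genes were lower. The mean of the list was -0.15 (p = 0.275, and p = 0.240 with an estimated correlation).

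The line nearest to R1 by correlation across genes was AH129-NC1, at 0.974, while the line nearest to CS1-1 was R1, at 0.970. Chromosome 8 genes had a median of -0.23 in ahES minus diploid ES, with 4 genes higher and 16 lower. This was carried mainly by R1, as the chromosome 8 median was also -0.34 in CS1-1 minus R1. Against the mean of the other lines it was 0.386 in R1, -0.05 in CS1-1 and -0.17 to -0.07 in the ahES lines. It is therefore no evidence of a difference between haploid and diploid cells.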
